A study of Mus musculus with 6 samples.

How the data were processed

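RNA was measured by paired-end, strand-directional poly(A) sequencing of 6 libraries of sorted mouse cones, 3 control and 3 cone-specific Bmal1 knockout, each made from 100 ng of RNA per the labels' protocols. The authors deposited 1 table of FPKM values (fragments per kilobase of transcript, scaled to library size), with 1 column per library. The submitters' processing notes name TopHat2 2.1.0, Cufflinks 2.2.1, HTSeq, DESeq2 and the build mm10, without their roles. Which of them gave the FPKM, which fragments enter that scaling, which annotation was used and whether strand was used in counting are not given in the sources used here. The table holds 9720 genes, all of type protein-coding, and each has a value above 1 FPKM in at least 1 library. No value lies under 0.1 FPKM, so 0.1 stands as a floor, and 389 genes have a library at it. None of the 13 protein-coding genes of the mitochondrial genome is in the table, so they were not analysed. A filter of this kind before deposit removes genes that were low in every library and can affect gene lists of rare cell types.

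Library depth is unknown, since FPKM keep no read total and whole reads could not be recovered from them. The FPKM sums cover part of each library and were not taken as depth. No counting interval or detection floor is therefore given, and precision is judged from the spread between libraries.

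Groups were taken from the genotype labels and replicate numbers from the sample titles. Gene IDs were matched to GENCODE vM21 (GRCm38, the same assembly as mm10) for position, length and GC content, with 9702 of 9720 matched and 18 not. Of these, 6644 had the same version. 15 symbols that a spreadsheet had stored as dates were restored through their gene IDs.

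Values were transformed as log2(FPKM + 1), genes with a mean of at least 1 FPKM over the 6 libraries were kept (8627 tested, 1093 below), and no further scaling was applied. Knockout and control were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a variance trend, two-sided), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Adjusted p-values in the text are from limma. Ratios of means are of FPKM. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

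Before the data were examined, 31 gene lists (522 entries, of which 370 are in the table) were fixed, together with the test, the alternatives and a rule for named genes. The rule takes Arntl and Cplx3, each tested clock activator and E-box target, and up to 12 called genes per direction without overlap between groups, filled to 6 with genes of smallest p that are said not to pass. From each list described it takes 2 to 4 members of smallest p and the most abundant one, and for markers of other cells the 2 most abundant. Which lists are described with examples was decided after the values were seen, and the values of some single list members are not reported here. Lists of at least 3 tested genes were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation, and with fry, adjusted over the 24 lists.

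The remaining lists gave the following adjusted p in camera, and none held a gene past the threshold over all genes. Cone transcription factors gave 0.73, membrane ion transport 0.73, thyroid hormone signalling 0.83, melatonin, dopamine and adenosine signalling 0.996, the retinoid cycle 0.75, the unfolded protein response 0.15, apoptosis 0.45, dissociation stress 0.98, Müller glia 0.48, bipolar cells 0.75, amacrine cells 0.75, ganglion cells 0.35 and sex-linked genes 0.16. Adjusted over the list alone, 1 apoptosis gene fell, Bcl2l1 (2.69 ± 0.60 and 1.11 ± 0.38 FPKM in control and knockout). Clock activators, horizontal cells, microglia and red blood cells had 2, 2, 1 and 1 tested genes, so their lists were not tested as sets. The red blood cell gene Alas2 measured 2.44 ± 0.83 and 4.45 ± 1.21 FPKM and passed as the single member of its list. Pigment epithelium and vascular markers had no tested gene.

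On simulated data with the means and spread of the 8627 genes, 50 genes each were shifted by log2 changes of 1, 1.5, 2 and 3. The fit recovered 64%, 100%, 100% and 100% of them, with 4 false calls among 186, and made 3 calls where no gene was shifted. The adjustment is looser with 186 calls than with the 9 calls of the real comparison, so these recovery shares do not carry over to it. Calu, at a log2 change of 1.68, did not pass there (adjusted p = 0.083, limma). A list of 17 genes shifted by 0.5 was found in 20 of 20 simulations, in which 6 of 460 tests of unshifted lists passed. The simulation draws genes independently, so it does not show how the set test behaves when genes vary together.

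Alternatives covered the pseudocount (0.1, 0.5), the filter (none, 5 FPKM), scaling, variance modelling, array weights, a rod marker covariate, the replicate number as a block, and each library left out. A correction for GC content and length (splines with 4 degrees of freedom each) was added after the data were seen. In the closing tests, the unadjusted limit for neighbouring genes and the rules for reading the tests of neighbouring genes, of Calu, of REV-ERB targets, of median-ratio scaling and of a GC trend set by genotype were set or tightened after their values were seen.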

Results

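Poly(A) RNA was profiled in cone photoreceptors of adult mice labelled as cone-specific Bmal1 knockouts or as controls. Cones were marked with eGFP through the Z/EG reporter, which fluoresces after Cre has acted, and were collected by FACS from dissociated neural retinas. The knockout animals carried 2 floxed copies of Bmal1 and the Cre transgene HRGPcre. The controls carried the same transgene and 1 floxed copy, so a control cone is heterozygous after recombination, although the series text describes the controls as wild type. There were 3 libraries per group. Animals lived in 12 h of light and 12 h of darkness, and the time of day of collection is not given in the sources used here. The age is labelled both as postnatal day 60 to 80 and as 2 to 6 months. The labels do not say whether a library came from 1 animal or from several, so p-values measure only the spread between these samples, which may be in part technical. The values were FPKM of 9720 protein-coding genes. Their sums ranged from 84995 to 128773 FPKM per library, which is not a read depth, and the depth is unknown. In control 3 the gene model Gm17364 held 10.03% of the sum, whereas the leading gene held 1.49% to 2.88% in the other 5 libraries.

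Arntl, the gene that encodes BMAL1, was measured first because it was the deleted gene. It lies on chromosome 7 from 113207465 to 113314126 on the plus strand (GRCm38, gene ID ENSMUSG00000055116.7). Its level was 2.96 ± 0.34 FPKM in control cones and 3.05 ± 0.66 FPKM in knockout cones (mean ± SD, n = 3 each). The libraries read 2.9998, 2.60 and 3.27 FPKM in control and 3.37, 2.28 and 3.48 FPKM in knockout. The log2 difference was 0.02 with a 95% interval from -0.45 to 0.50, and limma gave an adjusted p of 0.9996. The deposited value covers the whole gene, and the labels do not say which part is floxed, so the level does not check the genotype labels. Clock, the partner of BMAL1, measured 5.46 ± 1.22 and 6.14 ± 0.49 FPKM (adjusted p = 0.9996, limma).

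The comparison between the groups asked which cone transcripts depend on Bmal1, and the series title names Cplx3 as one of them. Of 8627 genes tested, 9 passed an adjusted p of 0.05 in limma, 4 higher and 5 lower in the knockout. The 5 lower genes were Nr1d1, Per3, Nr1d2, Gzmm and Cplx3. The 4 higher genes were Ndrg1, Dnah9, Gas7 and Cry1. For each of the 9 genes, the ranges of the 3 control and the 3 knockout values were apart. An unadjusted p under 0.05 was reached by 474 genes, where 431 would be reached by chance, and the groups were apart for 9.39% of tested genes against the 10% that chance gives for 3 against 3. After each library was rescaled to a sum of 1000000 FPKM, 6 genes were higher and 5 lower.

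**Figure D1:**
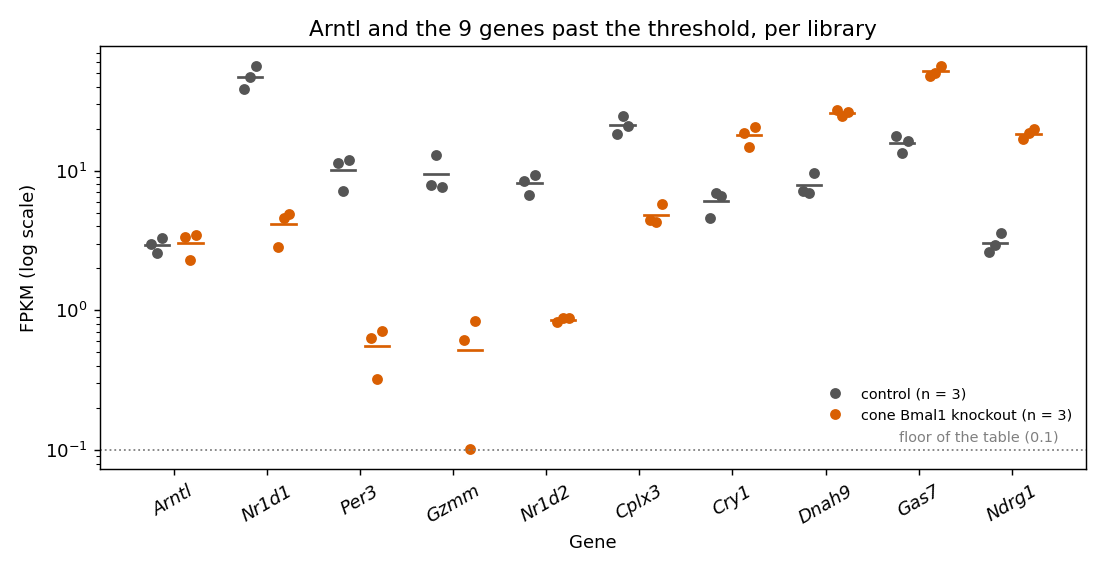
FPKM of Arntl and of the 9 genes past the adjusted threshold, on a logarithmic axis, with 1 point per library (3 control, 3 knockout) and a bar at each group mean. Nr1d1 lay between 38.3 and 56.2 FPKM in control and between 2.87 and 4.91 FPKM in knockout, while the groups overlapped for Arntl.

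Genes driven by BMAL1 through E-box elements held 4 of the 9 called genes. Nr1d1, which encodes the nuclear receptor and clock repressor REV-ERB alpha, fell from 47.2 ± 8.98 to 4.13 ± 1.11 FPKM (mean ± SD, n = 3 each). This was an 11.4-fold difference of means and a log2 change of -3.24 ± 0.25 (SE; adjusted p = 0.00013, limma). Nr1d2, which encodes REV-ERB beta, fell from 8.17 ± 1.35 to 0.860 ± 0.033 FPKM (log2 change -2.29 ± 0.21, adjusted p = 0.00030, limma). Per3, a period gene, fell from 10.1 ± 2.59 to 0.559 ± 0.207 FPKM (log2 change -2.81 ± 0.24, adjusted p = 0.00023, limma). Cry1, a cryptochrome that represses BMAL1 activity, rose from 6.03 ± 1.28 to 18.04 ± 2.87 FPKM (log2 change 1.44 ± 0.23, adjusted p = 0.042, limma). Log2 changes are on the scale of log2(FPKM + 1), which understates the change of genes near 1 FPKM. Whether both groups were collected at the same time of day is not known, so these clock gene changes cannot be told apart from a difference in it.

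Of the 16 E-box genes fixed for the list, 12 were tested. Over all genes, 3 fell and 1 rose, and 8 did not pass. Adjusted over the list alone, 4 fell and 1 rose, the additional one being Tef, which encodes a PAR bZIP transcription factor. Tef measured 40.8 ± 8.78 FPKM in control and 19.9 ± 3.06 FPKM in knockout (adjusted p = 0.31 over all genes, limma). Among the other members, the log2 differences were -0.47 for Hlf, -0.40 for Per1, -0.38 for Bhlhe41, -0.15 for Per2, 0.06 for Cry2, 0.13 for Usp2 and 0.14 for Ciart, all with an adjusted p of 0.897 or more in limma. Per2, Cry2 and Ciart changed sign with array weights and without control 1, Cry2 and Ciart also with the rod marker covariate, and Cry2 also without knockout 3. As a set the list shifted downward in limma's camera test with a preset correlation (adjusted p = 1.67e-05). This call was lost with an estimated correlation (adjusted p = 0.94 with an estimated correlation), and fry gave an adjusted p of 0.066 for a shift on balance and 0.00065 for change in either direction. The called genes went both ways, since Cry1 rose. These set tests include the called genes and were not run without them, so they do not speak for the other members. Over the 8 other clock genes tested, none passed over all genes, and adjusted over the list alone 1 rose, Nfil3, which encodes a bZIP repressor. Nfil3 measured 2.099 ± 0.956 FPKM in control and 5.46 ± 0.57 FPKM in knockout (adjusted p = 0.27 over all genes, limma). In the same list Rora, a nuclear receptor gene, measured 23.8 ± 4.403 and 30.6 ± 1.31 FPKM, with an adjusted p of 0.93 in limma. The set test of that list gave an adjusted p of 0.23 in camera.

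Cplx3 encodes complexin 3, a regulator of SNARE-driven vesicle fusion at ribbon synapses. It lies on chromosome 9 from 57599992 to 57606281 on the minus strand (GRCm38, gene ID ENSMUSG00000039714.8). It fell from 21.4 ± 3.14 FPKM in control to 4.82 ± 0.81 FPKM in knockout, a 4.44-fold difference of means (log2 change -1.94 ± 0.22, adjusted p = 0.0018, limma). The libraries read 18.5, 24.7 and 21.0 FPKM in control and 4.42, 4.29 and 5.76 FPKM in knockout. Of the 15 SNARE and complexin genes tested, Cplx3 alone passed, over all genes and adjusted over the list alone. The other complexins in the table, chosen after their values were seen, did not pass. Cplx4 measured 156 ± 58.7 and 160 ± 1.05 FPKM (log2 difference 0.11 ± 0.30), and its sign flipped with quantile normalization, with the rod marker covariate and without control 1. Cplx2 measured 4.26 ± 0.50 and 4.69 ± 1.58 FPKM. Snap25, the most abundant SNARE gene of the list, measured 369 ± 66.7 and 433 ± 64.2 FPKM (adjusted p = 0.9996, limma). Napa, which encodes alpha-SNAP, measured 13.03 ± 2.54 and 7.50 ± 1.68 FPKM (adjusted p = 0.65, limma). The median log2 difference of the list was 0.06, its mean was -0.17, and camera pointed downward with an adjusted p of 0.45, so the signs differ. With fry the list passed for change in either direction (adjusted p = 0.00076). That test includes Cplx3 and was not run without it, so it does not speak for the other members.

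Outside the clock and synapse lists, Ndrg1, an iron- and hypoxia-responsive gene, rose 6.03-fold, from 3.06 ± 0.50 to 18.5 ± 1.48 FPKM (log2 change 2.26 ± 0.21, adjusted p = 0.00030, limma). Dnah9, which encodes an axonemal dynein heavy chain, rose from 7.90 ± 1.53 to 26.1 ± 1.27 FPKM (log2 change 1.62 ± 0.22). Gas7, which encodes a cytoskeletal regulator, rose from 15.8 ± 2.198 to 51.4 ± 4.64 FPKM (log2 change 1.65 ± 0.22). Both had an adjusted p of 0.0084 in limma. Gzmm, which encodes the protease granzyme M, fell from 9.48 ± 3.001 to 0.517 ± 0.377 FPKM (log2 change -2.78 ± 0.27, adjusted p = 0.00033, limma). The 3 genes named next to fill each direction to 6 did not pass, though each did in some alternatives. Calu, which encodes the calcium-binding protein calumenin, measured 118 ± 31.9 and 379 ± 84.2 FPKM (adjusted p = 0.083, limma). Plk5, a polo-like kinase gene, measured 12.1 ± 0.30 and 4.04 ± 1.61 FPKM (adjusted p = 0.083, limma). Loxl4, a lysyl oxidase gene, measured 0.679 ± 0.231 and 3.06 ± 0.895 FPKM (adjusted p = 0.11, limma). Calu passed in 5 alternatives, with an adjusted p in limma from 0.0092 with array weights to 0.047 with median-ratio scaling, and without control 1 Plk5 and Loxl4 passed (adjusted p = 0.043 and 0.025, limma). Exons of Calu overlap those of Opn1sw by 397 bp and exons of Gas7 overlap those of Glp2r by 66 bp, on opposite strands, and the sources used here do not say whether strand was used in counting. Under limma the adjusted p of Dnah9 reached 0.12 without control 2, 0.062 without knockout 1, 0.058 without knockout 2 and 0.061 without knockout 3. That of Gas7 reached 0.12 without control 2, 0.071 without control 3, 0.062 without knockout 2 and 0.070 without knockout 3, and that of Cry1 0.17 and 0.21 without controls 2 and 3 and 0.21, 0.083 and 0.21 without knockouts 1, 2 and 3.

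Positions on GRCm38 were chromosome 11 from 98767932 to 98775333 for Nr1d1 and chromosome 14 from 18204054 to 18239127 for Nr1d2. Per3 lies on chromosome 4 from 151003652 to 151044665 and Cry1 on chromosome 10 from 85131700 to 85185064. Gzmm lies on chromosome 10 from 79689020 to 79695261 and Ndrg1 on chromosome 15 from 66929318 to 66969640. Dnah9 and Gas7 both lie on chromosome 11, from 65831282 to 66168551 and from 67455437 to 67688990.

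Cone phototransduction genes were abundant in both groups, and none of the 20 tested passed, over all genes or adjusted over the list alone. Opn1sw, which encodes the short-wavelength cone opsin, measured 981 ± 235 and 1947 ± 160 FPKM (log2 difference 1.01 ± 0.32, adjusted p = 0.65, limma). Opn1mw, the medium-wavelength opsin gene, chosen after its values were seen, measured 1092 ± 408 and 745 ± 62.1 FPKM (log2 difference -0.48 ± 0.34, adjusted p = 0.94, limma). Guca1a, which encodes a guanylate cyclase activator, measured 414 ± 94.1 and 254 ± 112 FPKM (adjusted p = 0.90, limma). Slc24a2, the cone sodium, calcium and potassium exchanger gene, measured 20.6 ± 3.03 and 31.2 ± 4.15 FPKM (adjusted p = 0.87, limma). The list had a median of -0.07, a mean of -0.01 and a camera direction upward with an adjusted p of 0.75, so the signs differ.

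Of 18 outer segment and connecting cilium genes tested, 11 had a positive log2 difference and none passed singly. The list shifted upward in camera (adjusted p = 0.0090), and this was lost with an estimated correlation (adjusted p = 0.94 with an estimated correlation) and with fry (adjusted p = 0.65). Rp1, which encodes an axonemal protein of the outer segment, measured 22.2 ± 2.50 and 31.2 ± 1.92 FPKM. Rpgr, a ciliary gene, measured 5.92 ± 1.13 and 9.17 ± 2.06 FPKM, and the actin-bundling gene Fscn2 measured 4.10 ± 0.73 and 7.45 ± 2.60 FPKM. Rpgrip1, the most abundant member, measured 167 ± 36.6 and 181 ± 16.0 FPKM. The camera call also ended with quantile normalization (adjusted p = 0.11) and without control 2 (adjusted p = 0.067). None of the 17 ribbon synapse genes tested passed. Sv2b, a synaptic vesicle gene, measured 191 ± 11.7 and 340 ± 98.2 FPKM (adjusted p = 0.81, limma), and its paralog Sv2a measured 4.92 ± 0.52 and 3.13 ± 0.97 FPKM (adjusted p = 0.90, limma). The adjusted p of the ribbon synapse set was 0.35 in camera.

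None of the genes tested in 4 lists of metabolism, translation and stress defence passed over all genes. Of 46 ribosomal protein genes tested, 34 had a negative log2 difference, with a median of -0.23, and none passed. Camera gave an adjusted p of 0.0031 downward, lost with an estimated correlation (adjusted p = 0.94 with an estimated correlation) and with fry (adjusted p = 0.84). Without control 2 its direction turned (adjusted p = 0.94), and without knockout 2 the adjusted p was 0.071. Rps15 measured 75.7 ± 10.8 and 39.5 ± 6.01 FPKM (adjusted p = 0.40, limma), and Rps14 measured 10.3 ± 5.53 and 4.53 ± 2.92 FPKM (adjusted p = 0.84, limma). Rpl30, the most abundant member, measured 67.8 ± 28.3 and 69.1 ± 11.6 FPKM. Of 15 oxidative stress defence genes tested, 13 were negative, and camera gave an adjusted p of 0.0031 downward, lost with an estimated correlation (adjusted p = 0.94 with an estimated correlation) and with fry (adjusted p = 0.34). Adjusted over the list alone 1 fell, Gsta4, a glutathione S-transferase gene, at 5.09 ± 2.37 and 1.16 ± 0.20 FPKM (adjusted p = 0.20 over all genes and 0.0011 without control 1, limma). Gpx4, a glutathione peroxidase gene, measured 36.9 ± 11.3 and 20.8 ± 6.73 FPKM (adjusted p = 0.81, limma), and Sod1, the superoxide dismutase gene, measured 41.8 ± 4.33 and 30.1 ± 5.02 FPKM. Glycolysis genes were negative for 17 of 21 tested, with an adjusted p of 0.15 in camera and of 0.00034 without control 1, against 0.94 with an estimated correlation and 0.84 with fry over all libraries. Bsg, which encodes basigin, measured 122 ± 29.95 and 67.0 ± 23.9 FPKM (adjusted p = 0.77, limma). Pfkl, a phosphofructokinase gene, measured 6.03 ± 1.94 and 3.06 ± 1.14 FPKM. Gapdh, the most abundant glycolytic member, measured 453 ± 114 and 386 ± 128 FPKM. Of 47 nuclear oxidative phosphorylation genes tested, 31 were negative, with an adjusted p of 0.16 in camera. For that list the adjusted p was 9.16e-07 without control 1 and 0.043 without knockout 1, and without control 2 its direction turned (adjusted p = 0.34), against 0.96 with an estimated correlation and 0.94 with fry over all libraries. Lower genes outnumbered higher ones in the whole table too, with 90 against 37 at an unadjusted p under 0.01, but the counts were 71 against 56 after median-ratio scaling and 58 against 42 after a correction for GC content and length that was chosen after the data were seen.

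**Figure D2:**
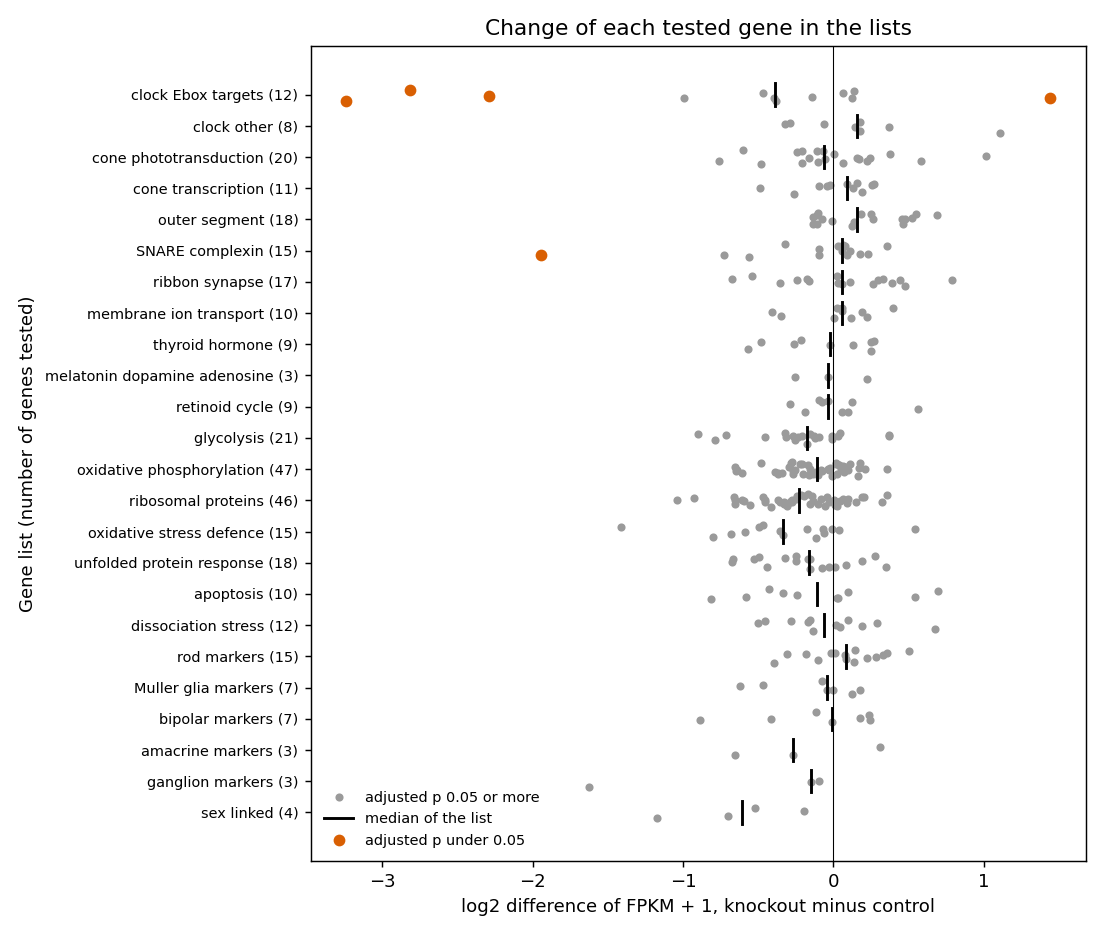
Log2 difference of FPKM + 1, knockout minus control, for each tested gene (points) of each gene list with at least 3 tested genes, with the list median as a bar and the number tested in brackets. Points past the adjusted threshold are 4 E-box genes and Cplx3, and the list medians lie between -0.61 and 0.16.

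Markers of rods differed widely in level and none of the 15 tested passed. The most abundant was Pde6g, a rod phosphodiesterase subunit gene, at 845 ± 113 and 676 ± 266 FPKM in control and knockout. Next was Sag, which encodes rod arrestin, at 686 ± 166 and 716 ± 92.5 FPKM. Other members were far lower, such as Nrl at 21.6 ± 6.58 and 27.7 ± 6.28 FPKM and Nr2e3 at 6.01 ± 0.54 and 7.97 ± 2.22 FPKM. The rod list gave an adjusted p of 0.24 in camera. Of other retinal cells, Car2 and Clu led the Müller glia markers, at 54.3 ± 10.6 and 26.0 ± 1.17 FPKM in control and 60.8 ± 6.67 and 18.6 ± 2.97 FPKM in knockout. None of the 7 Müller glia genes passed singly, and that list passed fry for change in either direction (adjusted p = 0.038). Lrtm1 and Cabp5 led the bipolar markers, at 28.3 ± 3.77 and 10.2 ± 5.61 FPKM in control and 32.1 ± 3.52 and 9.35 ± 0.95 FPKM in knockout. Adjusted over the list alone 1 of the 7 bipolar genes fell, Gng13, at 4.28 ± 1.79 and 1.79 ± 0.54 FPKM, and none passed over all genes. The ganglion cell marker Stmn2 read 21.1 FPKM in control 1 and 0.195, 0.668, 0.10, 0.10 and 0.240 FPKM in the other 5 libraries, and Nefl, the next marker, measured 1.42 ± 0.70 and 1.13 ± 0.24 FPKM. Control 1 also stood apart in correlation across genes, with a mean r of 0.90 to each group, and without it 13 genes passed, 5 higher and 8 lower. The Y-linked gene Eif2s3y read 13.4, 14.2 and 5.87 FPKM in controls 1 to 3 and 0.10, 17.7 and 5.37 FPKM in knockouts 1 to 3, so the balance of sexes differed between libraries.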

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

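Of the 9 called genes, Nr1d1, Per3, Gzmm, Cplx3 and Ndrg1 kept direction and call in each of the alternatives run, and so did Nr1d2 except under the filter of 5 FPKM, where it was not tested. Dnah9 and Gas7 lost their calls in 5 alternatives each and Cry1 in 8, always with the same direction. The cause was not tested for results that changed, except that leaving out a library leaves fewer samples. With a library left out, 6 to 13 genes passed, with 1 to 5 higher and 5 to 8 lower. Array weights, which give control 1 a weight of 0.31, called 23 genes, 11 higher and 12 lower. The replicate number as a block left 6 genes, 1 higher and 5 lower. It ended the calls of Dnah9 and Gas7 (adjusted p = 0.078 each, limma) and of Cry1 (0.23, limma). Cry1 was also lost with a pseudocount of 0.1 (adjusted p = 0.056, limma) and with the rod marker covariate (0.061, limma). Same-numbered libraries did not deviate together from their group means (correlations of -0.12, -0.085 and -0.034). In these deviations no library correlated best with its own number. Centring within groups of 3 ties the deviations to each other, so these values cannot exclude a pairing. Without centring, control 3 and knockout 3 had the highest r of all pairs (0.966), but each control was closer to knockout 3 than to the other knockouts. The GC content and length correction, chosen after the data were seen, called 10 genes.

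The number of lists past the threshold was 4 and became 7 with array weights and 2 to 6 with a library left out. It became 0 with an estimated correlation or with fry for a shift on balance. For change in either direction, fry passed the E-box list (adjusted p = 0.00065), the SNARE and complexin list (0.00076) and Müller glia markers (0.038). For the E-box list the adjusted p was 0.94 with an estimated correlation and 0.066 with fry. Before adjustment, camera with an estimated correlation gave a p of 0.041 for that list. It gave 0.086 for oxidative stress defence, 0.26 for outer segment and 0.44 for ribosomal protein genes. Glycolysis passed in camera with quantile normalization (adjusted p = 0.0087), array weights (0.0019), the rod marker covariate (0.019) and without control 1 (0.00034). Oxidative phosphorylation passed with the filter of 5 FPKM (0.038), quantile normalization (0.012), array weights (1.59e-07) and without control 1 or knockout 1. The unfolded protein response passed with array weights (0.039) and without knockout 1 (0.043), and sex-linked genes passed with the GC content and length correction (0.042) and without control 3 (0.023) or knockout 2 (1.07e-05). Over all libraries none of these 4 lists passed with an estimated correlation (adjusted p from 0.936 to 0.964) or with fry (from 0.62 to 0.94). Calu passed with the filter of 5 FPKM, rescaling, median-ratio scaling, no variance trend and array weights, Plk5 with that filter, array weights and without control 1, and Loxl4 with array weights, the GC content and length correction and without control 1. Gsta4 passed with array weights, the rod marker covariate and without control 1, Fabp7 with rescaling and array weights, and Smpdl3a with array weights. Of 44 reversed gene values, 0 passed the threshold in either setting. With array weights the log2 difference was 0.12 for Per2, -0.052 for Cry2, -0.13 for Ciart, -0.25 for Rpl30, -0.0021 for Sag, -0.018 for Glul, 0.060 for Cabp5, 0.11 for Rbpms and 0.14 for Lpl. With the rod marker covariate it was -0.026 for Arntl, -0.049 for Cry2, -0.060 for Ciart, -0.055 for Sag and -0.065 for Cplx4. The GC content and length correction gave -0.019 for Arntl and -0.013 for Rpl30. Cabp5 was 0.022 when rescaled to a sum of 1000000 FPKM, 0.013 with quantile normalization and 0.018 with median-ratio scaling, and Cplx4 was -0.012 with quantile normalization.

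With a library left out the log2 difference ranged from -0.059 to 0.17 for Arntl, -0.40 to 0.098 for Per2, -0.12 to 0.18 for Cry2, -0.26 to 0.37 for Ciart, -0.017 to 0.30 for Rpgrip1 and -0.49 to 0.058 for Gapdh. It ranged from -0.21 to 0.40 for Rpl30, -0.098 to 0.26 for Sag, -0.074 to 0.27 for Glul, -0.23 to 0.37 for Cabp5, -0.31 to 0.071 for Nefl and -0.28 to 0.17 for Rbpms. It ranged from -1.13 to 0.21 for Uty, -0.53 to 0.18 for Ddx3y, -0.12 to 0.28 for Cplx2, -0.18 to 0.38 for Cplx4 and -0.32 to 0.16 for Lpl.

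Set tests that turned direction gave these adjusted p, in camera unless fry is named. Array weights gave 0.99 for thyroid hormone genes and 0.77 for bipolar markers, the GC content and length correction 0.75 for thyroid hormone and 0.41 for dissociation stress, and quantile normalization 0.79 for cone phototransduction. The filter of 5 FPKM gave 0.92 for cone phototransduction, 0.18 for thyroid hormone, 0.32 for apoptosis and 0.91 for melatonin signalling, dissociation stress and bipolar markers. Melatonin signalling gave 0.89 with the rod marker covariate, 0.95 with fry, 0.99 with a pseudocount of 0.1 and 0.999 with one of 0.5, and dissociation stress 0.95 without a filter. With a library left out, these lists turned in some runs and kept direction in others, and over all 6 runs the adjusted p ranged from 0.34 to 0.98 for cone phototransduction, 0.75 to 0.92 for thyroid hormone, 0.75 to 0.97 for melatonin signalling, 0.65 to 0.997 for the retinoid cycle, 9.16e-07 to 0.45 for oxidative phosphorylation, 2.51e-08 to 0.94 for ribosomal proteins, 0.40 to 0.90 for dissociation stress, 0.34 to 0.9994 for bipolar markers and 1.07e-05 to 0.75 for sex-linked genes. Oxidative phosphorylation and ribosomal proteins turned without control 2 alone (0.34 and 0.94), the retinoid cycle without control 1 alone (0.997) and sex-linked genes without knockout 1 alone (0.75), so the lowest value of each came from a run that kept direction.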

Other observations

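The tests below were chosen after the patterns they address were seen, and the limit for the ratio after the GC and length correction alone was written before that ratio was computed. Fabp7, a brain fatty acid binding protein gene, measured 30.7 ± 7.86 FPKM in control and 72.4 ± 7.49 FPKM in knockout (mean ± SD, n = 3 each; adjusted p = 0.20, limma). Its neighbour Smpdl3a, a phosphodiesterase gene, measured 0.625 ± 0.317 and 2.201 ± 0.1072 FPKM (adjusted p = 0.24, limma).

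Of the 10 splits of the 6 libraries into 3 and 3, the real one gave 9 genes and the highest other gave 1. With 10 splits the share of splits with a count as large, here 1 of 10, cannot be under 0.05.

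Cry1 rose while Nr1d1 and Nr1d2, whose products repress Cry1, fell. A hypothesis is that loss of REV-ERB repression raised other known targets too. Among Fabp7, Nfil3, Clock, Lpl and Arntl, 4 of 5 log2 differences were positive, and limma's fry over the 5 gave an unadjusted p of 0.024. Arntl is itself the deleted gene, so its level may not reflect REV-ERB repression. The genes were picked with the values of Fabp7 and Nfil3 in view, and Clock, Lpl and Arntl each lay within 1 SE of 0, so this stays open and may reflect the choice of genes.

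Arntl measured alike in both groups, while Nr1d1, Nr1d2 and Per3 fell and Cry1 rose. For Nr1d1 the lowest control was 7.80 times the highest knockout, so no library lay within the range of the other group. Nr1d1 had the smallest p of all genes in this comparison, so it is not an independent check. A mislabelled library is therefore not excluded. That the value of the whole gene misses a deleted exon is a candidate explanation that stays open, since no value per exon was used here. The lower 95% limit of the log2 change in Arntl was -0.45.

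At an unadjusted p under 0.01, reached by 127 genes, 4 adjacent pairs had differences in the same direction, against a mean of 1.09 in 10000 shuffles: Fabp7 with Smpdl3a, Cdc34 with Gzmm, Gas7 with Glp2r, and Calu with Opn1sw, of which Gzmm and Gas7 alone passed the adjusted threshold. The share of shuffles with as many pairs was 0.025 at this limit, 0.0018 at 0.02 and 0.0017 at 0.05, but 0.055 at 0.005, so chance placement is not excluded at each limit tried. Reads shared between overlapping exons are argued against for the 2 pairs with no overlapping exon. They stay open for Calu with Opn1sw. The ratio of Calu to Opn1sw was 0.12 ± 0.010 in control and 0.197 ± 0.055 in knockout (mean ± SD), but with 0.0071 between the nearest libraries of the groups. Gas7 and Glp2r share 66 bp, against a Gas7 transcript of 7067 bp, which argues against shared reads for the rise of Gas7. For the rise of Glp2r they stay open. A GC content and length trend stays open: after the correction 3 of the 4 pairs stayed under 0.01, and recounted over all genes the share was 0.026 at 0.005, 0.0036 at 0.01 and 0.011 at 0.05, but 0.062 at 0.02. The correction also lowered the correlation (Spearman, across genes, which are not independent) between neighbours without a shared exon and under 10 kb apart from 0.16 to 0.053, and a shared effect of the genotype on a locus was not tested.

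At an unadjusted p under 0.01, lower genes outnumbered higher genes by 2.43 to 1, and the lower ones had a median GC content of 55.5% against 49.0%. After the GC content and length correction the ratio was 1.38, so much of the excess went with base composition or length. The correction removes any group difference that follows GC content or length, so it cannot tell a technical trend from an effect of genotype. After median-ratio scaling the ratio was 1.27, but scaling may move the ratio towards 1 by itself, which was not tested. The median log2 difference of all genes was -0.016 before scaling, so a level difference between the libraries stays open. Each library's deviation from the gene means over all libraries was correlated with GC content (Spearman, across genes, which are not independent). Such deviations are tied to each other, since the libraries share the mean, so positive values in some libraries go with negative ones in others. The correlations were 0.028, 0.30 and 0.23 in controls 1 to 3 and -0.23, -0.31 and 0.058 in knockouts 1 to 3. The lowest control minus the highest knockout was -0.031, less than the spread within a group, so whether genotype sets a GC trend in each library stays open.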
